A study of Mus musculus with 8 samples.

How the data were processed

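Foxa2 and Hdac3 were measured by ChIP-seq in liver of wild-type C57BL/6 mice at 3 and 21 months. Per the labels' protocols, chromatin came from snap-frozen liver, Foxa2 was precipitated with a rabbit antiserum and Hdac3 with a rabbit antibody, and the libraries were amplified by PCR, selected for short inserts on a gel and sequenced on an Illumina instrument. Per the labels, each protein and age had 2 libraries, and both libraries of a group name 1 list of sites. The 8 libraries were grouped by their titles. How the 2 libraries of a group were combined, whether they came from separate animals, and the read depth of each are not given in the sources used here.

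Per the submitters' processing notes, BWA was among the tools and mm9 was the genome build. The version and settings of BWA, the peak caller, the control library and the rule that set the length of each list are not given in the sources used here. Per the file headers, each site has a chromosome, a begin, an end, a fold enrichment and a q-value. The enrichment is a ratio per site made by the authors, and what it is relative to is not given in the sources used here. The q-values deposited with the sites reached 0.12 in both Foxa2 lists and 0.2 in both Hdac3 lists, and each list was sorted by q-value. Some sites had the same begin and end (144, 39, 144 and 94 sites in the young Foxa2, old Foxa2, young Hdac3 and old Hdac3 lists), so the end was counted as part of the site and a width is the end minus the begin plus 1 bp. Whether positions count from 0 or 1 is not given in the sources used here, and positions are printed as the lists give them.

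All values below start from these sites, and every site was used. Sites of 2 lists were called shared when they overlapped by at least 1 bp. Shares are given with exact (Clopper-Pearson) 95% intervals for counting error, and no interval or rotation takes the spread between animals or libraries into account. With 1 list per group no age difference was tested. Overlap between lists was set beside 1000 circular rotations of the sites of 1 list along each chromosome, between the first and last site of any list on it, or 200 rotations for alternatives and for distances between age classes. Rotation keeps the number, width and spacing of sites. The ratio of observed to rotated overlap has a Poisson interval in the tables and is a description of these lists. Foxa2 sites were put in 3 classes (young list only, old list only, both), and the share with an Hdac3 site in old-only minus young-only sites was set beside 10000 reassignments of the class within 5 quintiles of q rank. Regions held by all 4 lists were made by merging all sites that overlap by at least 1 bp.

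The score that ranks sites was the q-value, with ties put in order of enrichment. The plan named a score without saying which, and q was taken before overlaps were computed because the lists were sorted by it. The plan also fixed which sites are named. With no annotation of mm9 in use, these were the 4 sites with the best score for each protein and class, and for sites of both ages those with the best lower rank. Other places named were chosen after the values were seen.

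Alternatives fixed before the data were examined were an overlap of at least 50% of both sites, centres within 200 bp, edges within 500 bp, the 50% of each list with the best q, equal numbers of sites for both lists of a protein, autosomes, random placement in place of rotation, and medians of width and enrichment over sites found at both ages. Chosen after seeing the data were the lists without regions held by all 4 lists, equal numbers of sites ranked by enrichment, and q limits of 0.1, 0.05 and 0.01.

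The overlap counts were checked against bedtools 2.31.1 and were equal for 12 ordered pairs of lists. The procedure was tested on simulated data in which 200 overlaps were planted among randomly placed sites: 100% of them were found in each of 3 simulated pairs, and unrelated lists gave 6, 1 and 0 overlaps where 100 rotations gave means of 6.25, 1.64 and 0.6. Each planted site was centred on a site of the other list, so finding it was certain and checks the code only. The unrelated lists were placed at random, without the runs of the real lists, so rotation was not checked for crowded sites. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

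Planned results on gene lists, cell type markers, distance to transcription start sites and forkhead motifs were not run, because the gene table at hand was made for GRCm38, another build than that of the sites, and no mm9 sequence or annotation was used here. The gene lists fixed beforehand were therefore not used here, and no coordinates were converted.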

Results

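Chromatin immunoprecipitation with sequencing (ChIP-seq) located 2 proteins on the DNA of liver from C57BL/6 mice, a common inbred laboratory strain, at 3 months (young) and at 21 months (old). Foxa2 is a forkhead transcription factor that can bind closed chromatin and takes part in liver gene control, and Hdac3 is a histone deacetylase that works in corepressor complexes with nuclear receptors. The design asked where each protein lay on the genome at each age. Each protein and age had 2 libraries, 8 in all, and the libraries of a group were represented by 1 list of binding sites, 4 lists in all. The lists held 6604 sites for Foxa2 at 3 months, 12834 for Foxa2 at 21 months, 5828 for Hdac3 at 3 months and 2930 for Hdac3 at 21 months. Read depth per library was unknown. With 1 list per group no value had a replicate error, so no test of age was made, and the 95% intervals below are exact binomial intervals that cover counting error only. Positions are those of the mm9 build of the mouse genome as the lists gave them, and sites are named by position because no gene annotation of that build was used here.

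Foxa2 was listed at more sites in old than in young liver. The old list held 1.94 times as many sites as the young list, and its sites covered 1501 kb against 458 kb. The old list was also the longer one at stricter q limits. With q of at most 0.1, 0.05 and 0.01 it held 9734, 7059 and 3954 sites, against 6521, 5685 and 1393 in the young list, which gave ratios of 1.49, 1.24 and 2.84. The bar plot of sites at each q limit shows these numbers for both proteins. The size of the Foxa2 difference therefore varied with the q limit, and it has no replicate check.

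**Figure D1:**
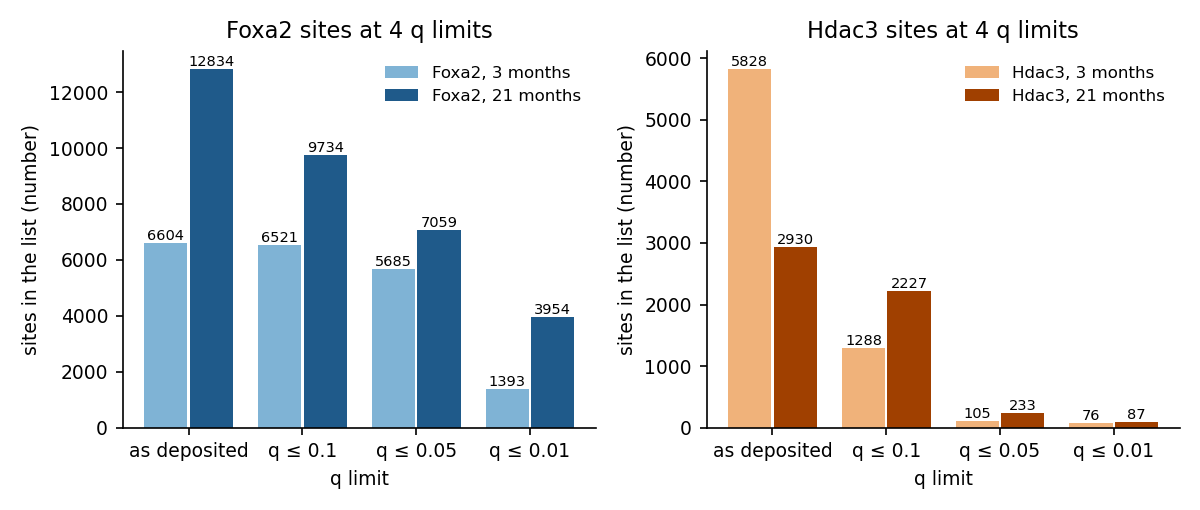
Number of sites (vertical axis) in the young and old lists of Foxa2 (left) and Hdac3 (right) as deposited and at 3 stricter q limits (horizontal axis), 1 list per bar. The old Foxa2 bar is the taller at each limit, from 12834 against 6604 sites to 3954 against 1393, whereas the old Hdac3 bar is the shorter as deposited, 2930 against 5828, and the taller at each stricter limit.

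The Foxa2 sites with the lowest q values were occupied at both ages. Of the 500 young sites with the lowest q, 96.6% overlapped an old site by at least 1 bp, and of the 500 such old sites 93.8% overlapped a young site. The share fell with rank. In the young list it ranged from 14.0% to 28.2% over the bins from rank 2501 on, with 21.2% in the last bin, and in the old list it reached 0.898% over the last 334 sites, as the plot of shared sites by q rank shows. Over the full lists, 2690 young sites overlapped an old site, 40.7% of the young list (95% interval 39.5 to 41.9), and 2690 old sites overlapped a young site, 21.0% of the old list (20.3 to 21.7). When the old sites were rotated along their chromosomes 1000 times, 6.18 young sites overlapped one on average and at most 18 did. The other 10144 old sites were in the old list only, and 3914 young sites were in the young list only. Many sites listed at 1 age lay close to a site of the other age. Of the old-only sites, 15.3% lay 500 to 10000 bp from a young Foxa2 site, against a mean of 4.36% in 200 rotations, and of the young-only sites 17.5% lay that far from an old site, against 7.49%. A shared share depends on what counts as overlap: when at least 50% of both sites had to overlap, 18.7% of young and 9.60% of old sites were shared.

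**Figure D2:**
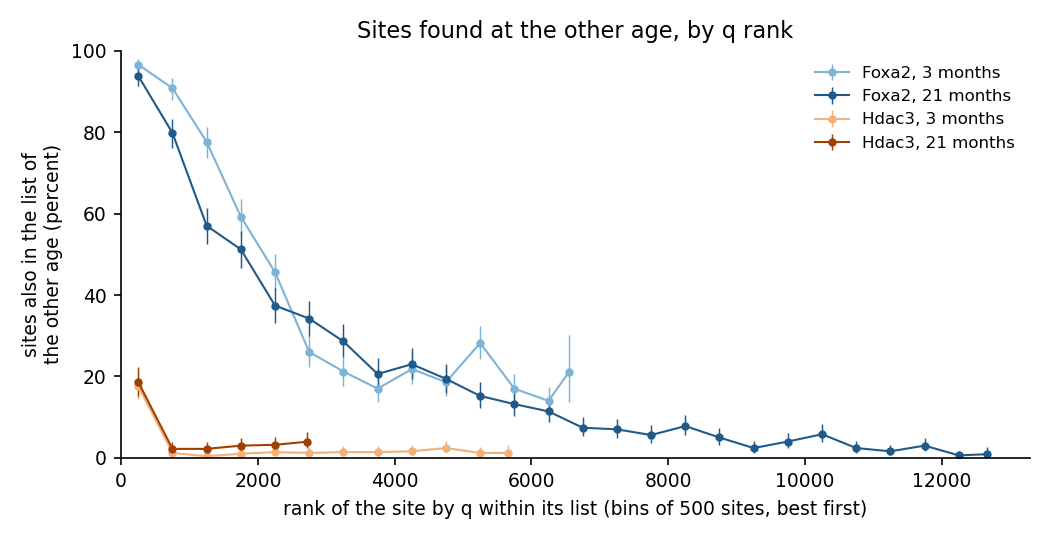
Percent of sites that overlap a site of the same protein at the other age (vertical axis) against the rank of the site by q within its own list (horizontal axis), in bins of 500 sites, with 95% exact binomial intervals for counting error. Both Foxa2 curves start above 90% and fall with rank, whereas both Hdac3 curves start under 20% and stay under 5% after the first bin.

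Old-only, young-only and shared Foxa2 sites differed in width and in chromosome. Old-only sites had a median width of 90.0 bp (quartiles 59.0 and 120.0) and 10.1% were under 30 bp, whereas young-only sites had a median of 21.0 bp (quartiles 8.25 and 46.0) and 60.3% were under 30 bp. Sites found at both ages had a median width of 83.0 bp in the young list and 161 bp in the old list. On the X chromosome lay 4.73% of the young-only sites (95% interval 4.08 to 5.44), 1.45% of the shared sites as drawn in the young list (1.03 to 1.98) and 0.660% of the old-only sites (0.512 to 0.838). Over the full Foxa2 lists the X share was 3.39% at 3 months and 0.849% at 21 months, and over the Hdac3 lists it was 5.23% and 6.01%. Of the old-only sites 19.2% had a q of at most 0.01, and of the young-only sites 3.81% did. The authors' enrichment per site had medians of 11.9 in the young and 22.3 in the old Foxa2 list, and 18.2 in the young and 15.9 in the old Hdac3 list. What the enrichment is relative to is not given, so the medians of different lists show no change of binding.

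The old-only Foxa2 sites with the lowest q lay on chromosome 8 from 127095687 to 127096354, with an authors' enrichment of 26.3 and rank 119 in the old list, on chromosome 13 from 47266123 to 47266447 (enrichment 29.1), on chromosome 9 from 31812981 to 31813264 (36.8) and on chromosome 18 from 5618616 to 5618795 (93.3). None of these 4 overlapped a site of the 3 other lists. The 4 young-only Foxa2 sites with the lowest q all lay on chromosome X between 166410786 and 166446856. Their ranks in the young list were 19, 27, 32 and 52, their enrichment ran from 3.53 to 9.20, and the widest measured 3648 bp. Each of them overlapped a site of the young Hdac3 list, and 3 of them a site of the old Hdac3 list. The best-ranked Foxa2 sites found at both ages lay on chromosome 17 from 39979918 to 39985792, on chromosome 15 from 74915916 to 74917507, on chromosome 9 from 3000000 to 3001509 and on chromosome 2 from 98502351 to 98503176. Their enrichment in the young list ran from 2.46 to 4.64, below the list's median, and all 4 were also in both Hdac3 lists. Outside the regions that all 4 lists held, the best-ranked shared Foxa2 sites lay on chromosome 4 from 137423288 to 137423453, chromosome 6 from 116585527 to 116585861, chromosome 8 from 129133776 to 129134052 and chromosome 16 from 93591733 to 93591971. These last 4 were chosen after the values were seen. Their enrichment in the young list ran from 15.7 to 47.0, and neither Hdac3 list held them.

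**Figure D3:**
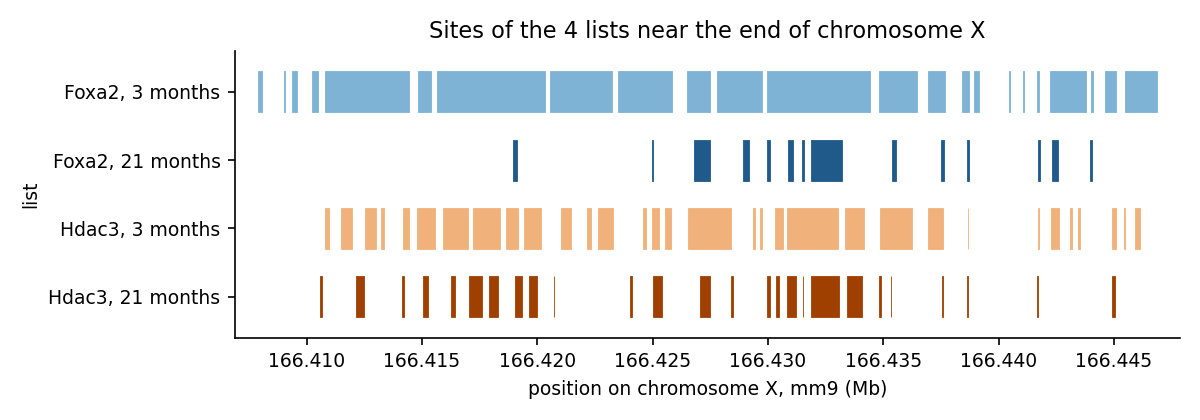
Sites of the 4 lists near the end of chromosome X, drawn to scale on mm9 positions in Mb (horizontal axis), 1 row per list. The young Foxa2 list has 23 sites here, the old Foxa2 list 14, the young Hdac3 list 32 and the old Hdac3 list 26, and the young Foxa2 sites cover 28.7 kb against 3.87 kb for old Foxa2.

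Hdac3 was listed at fewer sites in old than in young liver, but the direction turned at each stricter q limit tried over all regions. The old list held 2930 sites and the young list 5828, a ratio of 0.503. With q of at most 0.1 the old list was the longer one, with 2227 sites against 1288 (ratio 1.73), and it stayed so at 0.05, with 233 against 105 (ratio 2.22), and at 0.01, with 87 against 76 (ratio 1.14). Outside regions held by all 4 lists the numbers were 150 against 25 at 0.05 and 11 against 11 at 0.01. Of the young Hdac3 sites 77.9% had a q above 0.1, and of the old ones 24.0%. Most Hdac3 sites were narrow, with median widths of 26 bp at 3 months and 23 bp at 21 months, and 56.3% and 58.5% of them were under 30 bp.

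As deposited, the Hdac3 lists of the 2 ages had few sites in common, and most of these were places that Foxa2 lists held too. Of the young sites, 158 overlapped an old site, 2.71% of the young list (95% interval 2.31 to 3.16), and 163 old sites overlapped a young one, 5.56% (4.76 to 6.46). In 1000 rotations of the old sites, 0.602 young sites overlapped one on average and at most 6 did. Of the 500 sites with the lowest q, 17.6% of young and 18.6% of old sites were shared, and 85 of each 500 lay in regions held by all 4 lists. Of the shared sites, 112 in the young and 117 in the old list lay in regions that both Foxa2 lists held too. Outside those regions 46 young Hdac3 sites (0.806%) and 46 old ones (1.64%) were shared. Those regions hold sites of both Hdac3 lists by definition: 112 of the 120 young and 117 of the 125 old Hdac3 sites in them were shared. Leaving them out therefore lowers the shares in advance. With both lists held to a q of at most 0.1, 6.83% of young and 4.0% of old sites were shared, and 82 of these 88 young and 83 of these 89 old sites lay in regions held by all 4 lists. At 0.05, 67 of 105 young sites (63.8%) and 67 of 233 old sites (28.8%) were shared, and at 0.01 the shares were 75% and 65.5%. The sites shared between lists shortened to 0.05 or 0.01 lay in regions held by all 4 lists. Outside these regions 25 young and 150 old sites had a q of at most 0.05, and 4 of these young and 9 of these old sites overlapped a site of the other age's full list, 16% (95% interval 4.54 to 36.1) and 6% (2.78 to 11.1).

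The young-only Hdac3 sites with the lowest q lay on chromosome X from 166421027 to 166421451, from 166411491 to 166411955 and from 166442262 to 166442623, all on young Foxa2 sites and the last on an old one as well. The other lay on chromosome 17 from 4626285 to 4626572, on an old Foxa2 site only. The old-only ones lay on chromosome X from 73843905 to 73844495 and on chromosome 18 from 3010706 to 3010995, both on Foxa2 sites of both ages, and on chromosome 12 from 68160393 to 68160498 and on chromosome 5 from 37052169 to 37052303, both on Foxa2 sites of the young list only. The 4 old-only sites had enrichments from 2.03 to 114, the last on chromosome 5. The best-ranked Hdac3 sites of both ages were the broad site on chromosome 17 from 39979925 to 39985781, those on chromosome 2 from 98506358 to 98507531 and from 98502352 to 98503176, and that on chromosome 9 from 3000000 to 3001509. Foxa2 lists of both ages held sites at all 4 places.

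When the sites of the 4 lists were merged, 24844 regions resulted. Of these 21917 were in 1 list, 2687 in 2 lists, 137 in 3 lists and 103 in all 4. The 103 regions covered 68.2 kb, had a median width of 341 bp, and lay in part in tight runs. Of the 28 on chromosome 9, 23 lay in 1 run near its start, and of the 10 on chromosome X, 8 lay in 1 run near its end. The run on chromosome 9 began at position 3000000 in each list and ended between 3038284 and 3038289, with 27 to 30 sites per list and median enrichments from 3.33 to 4.31. On chromosome 1 between 90109721 and 90249652 the young Foxa2 list had 69 sites, the old Foxa2 list 19, the young Hdac3 list 38 and the old Hdac3 list 73. The runs on chromosomes 9 and X and this block were chosen after the values were seen.

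Foxa2 and Hdac3 were listed at the same places far more often than rotated lists were, at both ages, yet at a small share of Foxa2 sites. At 3 months 213 Foxa2 sites overlapped an Hdac3 site, 3.23% of the young Foxa2 list (95% interval 2.81 to 3.68). At 21 months 156 did, 1.22% of the old list (1.03 to 1.42). In 1000 rotations of the Hdac3 sites along their chromosomes the mean was 1.63 sites at 3 months and 2.53 at 21 months, and the highest 13 and 12, so that the observed numbers were 131 and 61.7 times the mean and no rotation reached them. Lists of different ages exceeded all rotations too. Here 237 young Foxa2 sites overlapped an old Hdac3 site, 257 times the mean, and 263 old ones a young site, 58.8 times. Rotation spreads sites over whole chromosomes, so exceeding it does not show that the 2 proteins bind together. Outside the regions held by all 4 lists, 110 young Foxa2 sites (1.69%) and 47 old ones (0.370%) had an Hdac3 site of the same age, 81.5 and 22.1 times the mean of rotations. Hdac3 also lay near Foxa2 without overlapping it. At 3 months 561 Foxa2 sites lay 500 to 10000 bp from an Hdac3 site, against a rotation mean of 260.0, and at 21 months 356 did, against 252. The lists behind the 2 ages differed in length, so the shares of the 2 ages were not compared by a test. With equal numbers of sites by q for each protein the share was 2.14% at 3 months and 1.76% at 21 months.

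Over all regions, Hdac3 of either age lay most often on Foxa2 sites found at both ages and least often on old-only Foxa2 sites. Among Foxa2 sites of both ages, as drawn in the old list, 6.28% had a young Hdac3 site (95% interval 5.39 to 7.27) and 5.24% an old one (4.43 to 6.15). Among old-only Foxa2 sites 94 of 10144 had a young Hdac3 site, 0.927% (0.749 to 1.13), and 15 had an old one, 0.148% (0.0828 to 0.244). Among young-only Foxa2 sites 65 of 3914 had a young Hdac3 site, 1.66% (1.28 to 2.11), and 102 had an old one, 2.61% (2.13 to 3.15). Outside the regions held by all 4 lists, the shares at Foxa2 sites of both ages were 2.45% for young and 1.24% for old Hdac3, so that old Hdac3 there lay most often on young-only Foxa2 sites, at 2.58%. Those regions hold both Foxa2 lists and both Hdac3 lists by definition, so leaving them out lowers the shares at Foxa2 sites of both ages in advance.

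For Hdac3 of either age, the old-only share of 1.04% was set against the young-only share of 3.37%, a difference of -2.33 percentage points. In 10000 random reassignments of the class among Foxa2 sites of the same q-rank quintile, the central 95% of differences ran from -0.185 to 0.863. None was as low as the observed one. The differences for young Hdac3 (-0.734) and for old Hdac3 (-2.46) also lay below their reassignments. These percentiles describe the lists and are not a test of age. Outside 18 windows of 100 kb that held 6 or more sites of an Hdac3 list, chosen after the values were seen, the shares for young Hdac3 were 0.952% at young-only and 0.909% at old-only Foxa2 sites, with overlapping intervals, while those for old Hdac3 were 1.40% and 0.119%.

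**Figure D4:**
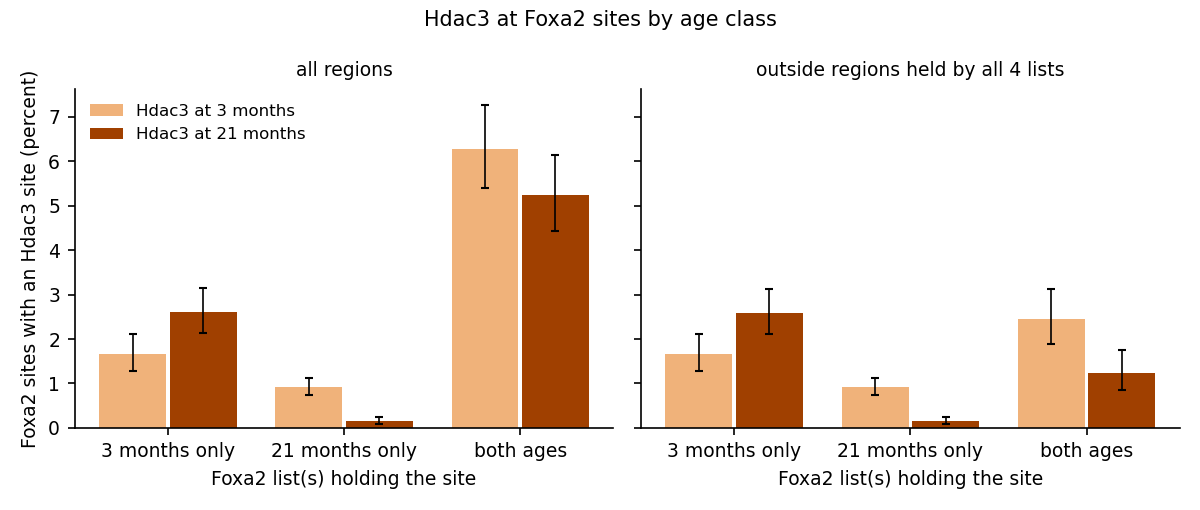
Percent of Foxa2 sites that overlap an Hdac3 site of the young or old list (vertical axis), for Foxa2 sites listed at 3 months only, at 21 months only or at both ages (horizontal axis), over all regions (left) and outside regions held by all 4 lists (right). Bars are shares and error bars 95% exact binomial intervals for counting error, and old Hdac3 lies at 2.61% of young-only and at 0.148% of old-only Foxa2 sites over all regions.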

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

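The tests of explanations in this part were chosen only after the results were seen, namely those on stricter q limits, site widths, regions held by all 4 lists, Foxa2 lists of the Hdac3 length, mean q and crowded windows. The shares of Hdac3 on each class of Foxa2 site and the Hdac3 share in lists of equal length were planned.

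The number of listed sites moved in opposite directions with age in the 2 proteins, 1.94 times as many at 21 months for Foxa2 and 0.503 times as many for Hdac3. This was noted because the direction differs between the proteins under the same comparison, and the difference was not tested, as each group had 1 list. The loose q limit of the lists may account for the Hdac3 direction, since with q of at most 0.1 the old list was 1.73 times as long as the young one. It does not account for the Foxa2 direction, where the lowest ratio over 3 stricter limits was 1.24. Deeper or more efficient old Foxa2 libraries stay open: Foxa2 sites of both ages, outside regions held by all 4 lists, were 1.98 times as wide in the old list, which more reads and more Foxa2 on the DNA would both produce, so that these, a gain of Foxa2 binding with age included, cannot be told apart without read depths and were not tested further. Inside regions held by all 4 lists the order turned, with median Foxa2 widths of 185 bp in the old and 305 bp in the young list. The old sites were therefore not wider everywhere, and the cause of this was not tested.

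Hdac3 sites were rarely shared between the ages in the lists as deposited, with 2.71% of young sites found in the old list. With both lists held to a q of at most 0.1, 0.05 and 0.01 the shares were 6.83%, 63.8% and 75%. Outside regions held by all 4 lists 6 of 1201, 0 of 25 and 0 of 11 young sites were shared at these limits. Such regions hold both Hdac3 lists by definition, so leaving them out removes shared sites and lowers these counts in advance. List length alone does not account for the rare sharing: young and old Foxa2 lists shortened to their best 2930 sites, the length of the old Hdac3 list, shared 47.7% of the young sites, against 3.89% for Hdac3. The lists so matched in length differed in q. It was at most 0.0272 in the young and 0.00323 in the old Foxa2 list, but reached 0.2 in the old Hdac3 list. With q of at most 0.01, 75.8% of young Foxa2 sites were shared (1056 of 1393), against the 75% of young Hdac3 sites (57 of 76). These close shares rest on unlike places. All 57 shared Hdac3 sites lay in regions held by all 4 lists, whereas 1301 of the 1393 young Foxa2 sites lay outside them. False sites at the rate that the q values state would not be enough, since the mean q of the young Hdac3 sites was 13.0% whereas 97.3% of them were not shared. Outside regions held by all 4 lists, a choice that lowers sharing, 4 of the 25 young and 9 of the 150 old sites with q of at most 0.05 were in the other full list. The shared sites may reflect signal that does not depend on the antibody, as 70.9% of the young ones (95% interval 63.1 to 77.8), and 79 of the 83 with q of at most 0.05 that were in the full old list, lay in regions that both Foxa2 lists held as well. A movement of Hdac3 with age, a false rate above what q states and sites missed in either list all stay open, and none was tested.

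Old Hdac3 sites lay on 2.61% of young-only and on 0.148% of old-only Foxa2 sites. Crowded windows where several lists place sites hold part of this. Outside the 18 windows of 100 kb with 6 or more sites of an Hdac3 list the shares were still 1.40% (95% interval 1.05 to 1.83) and 0.119% (0.0613 to 0.207). This argues against these 18 windows as the whole cause. Windows crowded with Foxa2 sites alone were not left out. On chromosome 4 from 146800000 to 146900000, for example, 9 young Foxa2 and 4 old Hdac3 sites stayed in, and on chromosome 16 from 3100000 to 3200000 6 and 4 did. Crowding in such windows therefore stays open. An exchange of the age labels of 1 protein could give the higher share of old Hdac3 on young-only sites. It would also put young Hdac3 on old-only Foxa2 sites more often than on young-only ones. Over all sites these shares were 0.927% (0.749 to 1.13) and 1.66% (1.28 to 2.11), which runs against it, but outside the 18 windows they were 0.909% and 0.952% with overlapping intervals. Outside both the 18 windows and regions held by all 4 lists, 73 young Foxa2 sites overlapped an old Hdac3 site and 77 a young one. These counts were close although the old Hdac3 list was the shorter, with 2648 sites against 5580. Over the rotation mean, which keeps the length of each list, they were 122 (95% Poisson interval 95.8 to 154) and 65.9 (52.0 to 82.3) times. That order runs with the exchange. Of the old Foxa2 sites, 150 overlapped a young Hdac3 site, 37.2 times the mean (31.5 to 43.7), and 35 an old one, 17.4 times (12.1 to 24.2), which runs with it too. The shares of young Hdac3 over all sites run against the exchange, so it cannot be told apart from correct labels by these values. A difference between ages in how the proteins share sites stays open as well, as does a batch shared by libraries of different age, of which the labels used here say nothing, and neither was tested.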

How the results depend on the processing

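The q limits, the lists without regions held by all 4, and the ranking by enrichment were chosen after seeing the data. Read depth, unknown here, limits every comparison of list lengths. No paired analysis was possible because each group had 1 list for its 2 libraries, for which reason leaving out a replicate was not run either, and alternatives that need genes, start sites or motifs were not run. The ratio of old to young sites is fixed by construction with 50% of each list or equal numbers, so it was not computed there. For Foxa2 it was 1.24 with q of at most 0.05 and within 1.5 times the reported value in the other 4 alternatives, and for Hdac3 it turned to 1.73, 2.22 and 1.14 with q of at most 0.1, 0.05 and 0.01. The shares below come in this order: young Foxa2 found in old, old Foxa2 found in young, young Hdac3 found in old, old Hdac3 found in young, young Foxa2 with young Hdac3, old Foxa2 with old Hdac3. As reported they were 40.7%, 21.0%, 2.71%, 5.56%, 3.23% and 1.22%. With 50% overlap of both sites they were 18.7%, 9.60%, 1.92%, 3.82%, 1.94% and 0.787%, and with edges within 500 bp 43.1%, 22.6%, 3.52%, 7.47%, 5.19% and 1.65%. With centres within 200 bp the share of young Foxa2 with Hdac3 was 3.82%, and the other 5 stayed inside their intervals, as all 6 did on autosomes. In the 50% of each list with the best q they were 56.5%, 29.1%, 3.23%, 6.35%, 3.91% and 1.46%, and with equal numbers by q 36.8%, 36.8%, 3.89%, 4.06%, 2.14% and 1.76%. With equal numbers by enrichment they were 24.7%, 24.6%, 1.02%, 1.06%, 0.818% and 0.530%, and without regions held by all 4 lists 39.8%, 20.2%, 0.806%, 1.64%, 1.69% and 0.370%. With q of at most 0.1 they were 39.8%, 26.6%, 6.83%, 4.0%, 1.67% and 1.26%, with 0.05 41.2%, 33.1%, 63.8%, 28.8%, 1.48% and 1.20%, and with 0.01 75.8%, 26.7%, 75%, 65.5%, 4.67% and 1.59%. These Hdac3 shares rest on the few sites that pass, 105 and 233 at 0.05 and 76 and 87 at 0.01. Regions held by all 4 lists hold overlapping sites by definition, so leaving them out lowers the shares in advance. The overlap of Foxa2 and Hdac3 exceeded every rotation or placement in all 12 alternatives at each age, from 20.9 to 4333 times the mean at 3 months and from 12.6 to 969 times at 21 months. The highest ratios came with q of at most 0.01, where few Hdac3 sites were left. All 12 alternatives spread sites over whole chromosomes, which every pair of lists exceeded, so their agreement is no sign of joint binding. The old-only minus young-only difference in Hdac3 stayed negative throughout, and inside its reassignments only for young Hdac3 with equal numbers by enrichment (-0.000525 percentage points) and with q of at most 0.1 (-0.104). It ran from -3.23 to -0.000525 for young Hdac3, from -6.49 (q of at most 0.01) to -0.717 (0.05) for old Hdac3 and from -8.87 to -0.893 at the same limits for either list. None of these alternatives left out the 18 crowded windows. Outside them the young Hdac3 shares were 0.952% at young-only and 0.909% at old-only Foxa2 sites, with overlapping intervals. Over sites of both ages, median widths were 83.0, 161, 160 and 167 bp and median enrichments 12.7, 27, 4.75 and 4.37 in the young Foxa2, old Foxa2, young Hdac3 and old Hdac3 lists. Where a share moved, the cause was not tested.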

Other observations

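The places and pairs in this part were chosen after their values were seen. In the old Foxa2 list 177 windows of 100 kb held 6 or more sites (1283 sites in all) and in the young list 25 did (312 sites), but the old list was 1.94 times as long. With 6604 sites in both lists, the old list had 27 such windows by best q and a mean of 20.3 in 200 random draws (11 to 28), so no excess was seen at equal length. On chromosome 9 from 46000000 to 46100000 the old list had 15 Foxa2 sites and the young list 4, with a median enrichment of 13.5 in the old list. On chromosome 1 from 40200000 to 40300000 the numbers were 12 and 2, on chromosome 7 from 35900000 to 36000000 they were 12 and 5, and on chromosome 18 from 85000000 to 85100000 they were 11 and 8. Elsewhere the young list was the denser one. On chromosome 8 from 19900000 to 20000000 it had 25 Foxa2 sites against 8, with 15 young and 24 old Hdac3 sites in the same window, and on chromosome 4 from 145700000 to 145800000 it had 18 against 1, with 3 young and 1 old Hdac3 sites. On chromosome 4 from 42900000 to 43000000 Hdac3 had 12 young and 9 old sites, against 4 young and 0 old Foxa2 sites.

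Foxa2 and Hdac3 also shared sites across ages. Outside the regions held by all 4 lists, 131 young Foxa2 sites overlapped an old Hdac3 site, 178 times the mean of 1000 rotations (95% Poisson interval 149 to 211), and 110 overlapped a young one, 81.5 times (67.0 to 98.3). Of the old Foxa2 sites there, 157 overlapped a young Hdac3 site, 39.1 times the mean (33.2 to 45.7), and 47 an old one, 22.1 times (16.2 to 29.4). With the crowded windows of Hdac3 left out as well, the 131 and 110 overlaps became 73 and 77, and the 157 and 47 became 150 and 35. Merged regions with young Foxa2 and old Hdac3 alone numbered 65, with a median Foxa2 enrichment of 5.29, and 3.08% of them lay on chromosome X. Regions with old Foxa2 and young Hdac3 alone numbered 91, with a median Foxa2 enrichment of 19.7, and none lay on chromosome X. Examples of the latter are the young Hdac3 sites on chromosome 17 from 4626285 to 4626572 and on chromosome 3 from 21885656 to 21885949, with enrichments of 14.3 and 23.1.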
